A study of Mus musculus with 8 samples.

How the data were processed

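Islets of 2 NFATc2 knockout mice and 2 wild-type mice, each untreated and with a cytokine cocktail in raised glucose, gave 8 libraries in 4 groups. Per the labels, RNA was extracted with Trizol and libraries followed standard Illumina protocols; whether reads keep strand is not given in the sources used here, so genes that overlap on opposite strands cannot be told apart. Related immunoglobulin segments and histone genes share sequence, and how reads that fit several of them were counted is not given either. The submitters' processing notes name HISAT2, HTSeq, DESeq2 and the build GRCm38, without versions or roles.

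The authors deposited 4 tables of their own comparisons over the same genes: cytokine over untreated in the genotypes they call KO and Mut, and KO over Mut untreated and with cytokines. No label uses the name Mut, and it was taken for wild type because it is the remaining genotype. The deposited signal columns hold means of read counts divided by a size factor per library, over the libraries of a group or over all 8. The log2 fold change and the score, a Wald statistic, come from the model of the authors, and the standard error was taken as the log2 fold change over that score. The p-values are the two-sided normal probabilities of the score in the deposited tables, and the deposited FDR equals a Benjamini-Hochberg adjustment over all of them. The smallest mean over all libraries was 23.2 normalized counts, so a filter on low genes had been applied before deposit. Gene symbols were taken from the table whose symbols a spreadsheet had not altered, and positions and gene types from GENCODE release M21 on GRCm38, in which 22 identifiers had no match.

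Because the tables hold no library columns, the test fixed before the data were examined for that case was used: a gene was called when the authors' FDR was below 0.05. Also fixed before the data were examined were the alternatives listed under the planned settings, the gene lists and the rule for named genes. That rule takes Nfatc2, the 8 largest changes per direction among calls with a mean of at least 50, the 4 smallest p-values per direction, and the 3 members with the smallest p of each list that was called or held at least 3 calls. It also takes the 6 smallest p-values of the interaction and names Ins1, Ins2, Gcg, Sst and Cxcl10. Genes named only from the fits of recovered reads, such as Tnfaip3, Selp, Il11 and mt-Rnr2, were chosen after their values were seen. The interaction was tested per gene as the difference of the 2 cytokine fold changes over the root of their summed squared standard errors.

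The 23 lists cover NF-κB signalling and inflammation, chemokines, interferon response, NFAT and calcineurin, beta, alpha, and delta, PP and epsilon cells, acinar, duct, endothelial, stromal, macrophage and lymphocyte markers, ER stress, immediate-early genes, apoptosis, oxidative stress, proliferation, calcium and exocytosis, heat shock, erythroid, sex-linked and mitochondrially encoded genes. Each list with at least 5 measured members was tested with cameraPR of limma 3.58.1 in R 4.3.3 on the deposited Wald statistic, two-sided, with a preset correlation of 0.01 and adjustment over the 22 lists tested. Of the 88 results 40 were called, 10 and 13 for the cytokine responses in KO and Mut and 9 and 8 for the genotype differences untreated and with cytokines. With the correlation estimated from the recovered reads, 0 were called in each comparison, with smallest adjusted p-values of 0.223, 0.312, 0.0969 and 0.0565. The rotation test fry, which asks whether the members of a list move 1 way on balance, called 0, 0, 1 and 6. Untreated it called proliferation (adjusted p 0.0042). With cytokines it called proliferation (adjusted p 0.0016) and lymphocyte, macrophage, endothelial, oxidative-stress and heat-shock genes (adjusted p 0.034 to 0.041). These calls come from the fit with the sex covariate, whose p-values are too small, as said below. List tests with few mice rest on the preset correlation, and members of a cell-type list move together when the makeup of a preparation differs. For proliferation genes the estimated correlation was -0.0008 untreated and -0.0013 with cytokines in the genotype comparisons. Both lay below the preset 0.01, so a lost call is not always due to correlation. For interferon-response genes in the KO cytokine response the estimated correlation was -0.0036, yet the adjusted p went from 4.6e-11 with cameraPR to 0.223. Tests with an estimated correlation also used the recovered reads in place of the deposited score, in fits with few residual degrees of freedom.

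After the tables had been seen, whole reads were recovered from them. A deposited group mean is the sum of 2 whole numbers, each times a fixed step, and the printed digits settle both numbers for 16268 genes (99.6%). Of these, 173 were settled only through the mean over all libraries. For the other 16095, with 1 solution in every group, the mean over all libraries was met to a relative tolerance of 1e-13. The 65 genes left out were mostly abundant, Ins1, Ins2, Gcg and Sst among them, and held 25.5% to 26.3% of normalized counts, so shares of a library are given over recovered genes. On simulated data 3990 of 4000 genes were settled and 0 of them wrongly. Size factors lay between 0.752 and 1.35, and the libraries held 13338383 to 24692555 recovered reads. Counting error, relative to the count, is largest for the genes with the lowest counts. Libraries within a group were told apart by 4 Y-linked genes and joined into mice within a genotype by sex, so which is replicate 1 or 2 of the labels is unknown; deviations of the joined libraries from their group means correlated at 0.77 in KO and 0.775 in Mut over 14182 genes.

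The recovered reads were tested with limma (voom, with the size factors of the authors) in 3 ways, all added after seeing the data: 4 group means without a covariate, the mouse as a block for the cytokine responses, and the sex of the mouse as a covariate for the genotype differences. The last treats the 2 libraries of a mouse as independent, which makes its p-values too small, and the block leaves 2 residual degrees of freedom. Data were simulated with 100 genes changed by log2 1 and 100 by log2 2 in the KO response alone. The fit of group means recovered 4% and 99% with 0 false calls, and the block 81% and 100% with 9 false calls. The fit of both genotypes together recovered 10% and 86% with 2 false calls. No response in both genotypes was simulated, so these shares do not give its recovery of a shared response. The simulated genes varied independently with 1 dispersion for all, and only genes with a mean above 50 were changed. Real libraries of a mouse can also differ in makeup, so the shares and false calls hold for the simulated setting only. Planned settings were FDR thresholds of 0.01 and 0.1, an absolute log2 fold change of at least 1, a mean of at least 50, centring on the median fold change, adjustment recomputed without a filter, the interaction taken from the genotype comparisons, and ranks or a preset correlation of 0.05 for the lists. Added settings were the fits above, leaving out each library, each mouse, the KO female mouse or the immunoglobulin segments, and list tests in the fits of recovered reads. Values per library on the log2 scale used a pseudocount of 1. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 did the rest.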

Results

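RNA was sequenced from isolated mouse pancreatic islets, the clusters of endocrine cells that hold the insulin-producing beta cells. Per the labels, NFATc2, a transcription factor activated by the calcium-dependent phosphatase calcineurin, had been deleted by tamoxifen in insulin-expressing cells of 2 adult mice, and 2 wild-type mice had received tamoxifen without a resulting deletion. Islets of each of the 4 mice were divided into an untreated culture and a culture kept for 2 h with cytokines, after a night in 5.5 mM glucose. The cytokines were IL1β at 5 ng/mL, TNFα at 10 ng/mL and IFNγ at 50 ng/mL, in 11 mM glucose. This gave 8 libraries in 4 groups of 2, in which the replicate is the mouse. The cytokines and the raised glucose were given together, so their effects were not separated. The deposited tables name the genotypes KO and Mut. Mut matches no label and was taken for the wild-type mice because they are the remaining genotype, and that name is kept here. The libraries held 13338383 to 24692555 reads assigned to the 16268 genes whose whole reads could be recovered from the deposited group means. Every group held 1 library from a female and 1 from a male mouse, as shown by 4 Y-linked genes, so sex was balanced between the groups.

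Nfatc2 itself (ENSMUSG00000027544, chromosome 2, 168476410 to 168601657, minus strand, GRCm38) was present in every library. Untreated libraries held 1167 and 842 normalized counts of Nfatc2 in the KO mice and 1557 and 1270 in the Mut mice, female before male. After cytokines the values were 987 and 899 in KO and 1646 and 1144 in Mut. The group means were 1005 ± 230 (SD, n = 2) against 1413 ± 203 untreated and 943 ± 62.1 against 1395 ± 355 with cytokines. In the authors' deposited table the KO over Mut log2 fold change was -0.49 (SE 0.23, p = 0.0359, FDR 0.903) untreated and -0.56 (SE 0.24, p = 0.0163, FDR 0.474) with cytokines, neither past an FDR of 0.05. With the sex of the mouse as a covariate, limma gave adjusted p-values of 0.07 and 0.0403 for log2 fold changes of -0.50 and -0.54. The labels do not give the deleted exons, and islets hold other cell types, so a count over the whole gene is a limited check of the deletion. The response of Nfatc2 to cytokines was -0.09 (SE 0.26) in KO and -0.02 (SE 0.26) in Mut islets in the authors' deposited tables. The authors called none of the 18 measured members of the list of NFAT and calcineurin genes in any of the 4 comparisons, and limma with the sex covariate called 1, Nfatc2 with cytokines. Their medians were 0.01 and 0.02 for the cytokine responses and 0.04 in both genotype comparisons.

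**Figure D1:**
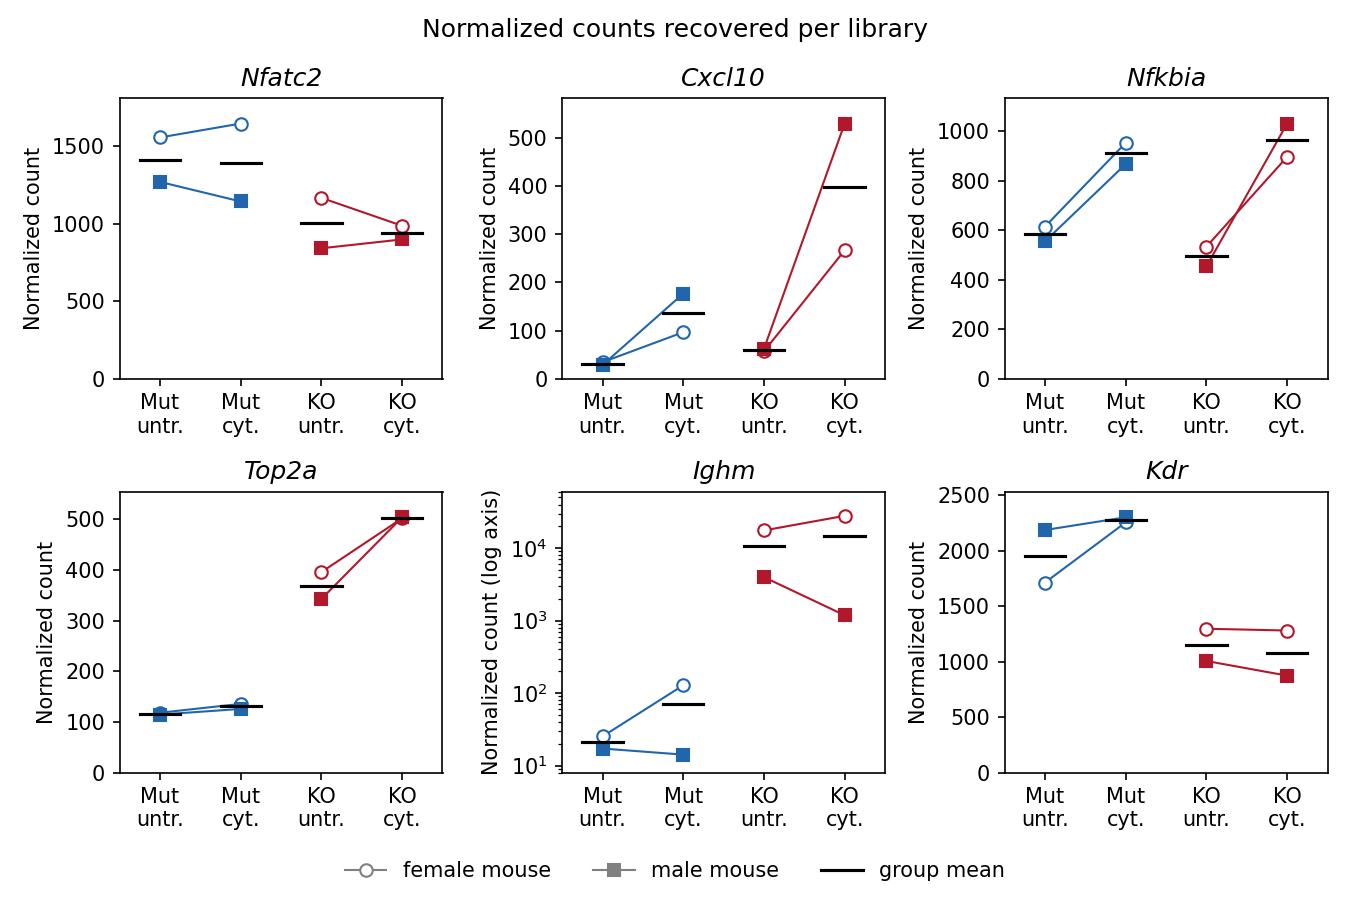
Normalized counts recovered per library for 6 genes (vertical axes, counts divided by size factors; logarithmic for Ighm) in the 4 groups (horizontal axis, Mut and KO, untreated and with cytokines). Each line joins the libraries of 1 mouse, open circles stand for female and filled squares for male mice, and black bars are group means; Cxcl10 reached 266 and 529 counts in the KO cytokine libraries and 96.7 and 177 in those of Mut.

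In KO islets linker histone genes, a chemokine gene, NF-κB targets and a metallothionein gene were higher with cytokines. Cxcl10, a chemokine induced by interferon γ, rose 6.6-fold in the authors' deposited table (log2 2.72, SE 0.48, FDR 0.000146). Its mean went from 59.5 ± 3.63 to 398 ± 186 normalized counts in the recovered libraries (SD, n = 2). Nfkbia, the inhibitor that NF-κB induces against itself, rose 1.95-fold (log2 0.96, SE 0.18, FDR 0.000771), and Birc3, an NF-κB target that restrains cell death, rose 1.82-fold (log2 0.86, SE 0.18, FDR 0.00335) in the authors' deposited table. The linker histone gene Hist1h1d had the smallest FDR (log2 0.85, SE 0.14, FDR 3.5e-05) in the authors' deposited table. Hist1h1e rose by 0.56 (SE 0.13, FDR 0.0332) and the metallothionein Mt1 by 0.78 (SE 0.16, FDR 0.00383) in the authors' deposited table. The only gene the authors called lower was Ppy, which encodes pancreatic polypeptide. It fell by 0.84 on the log2 scale (SE 0.16, FDR 0.000475) in the authors' deposited table. Its recovered values went from 31760 to 19795 normalized counts in the female and from 29544 to 14842 in the male mouse.

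These 7 genes, 6 higher and 1 lower, were the calls at FDR below 0.05 in the authors' deposited table for KO islets, where 166 genes had an unadjusted p below 0.05. With the mouse as a block, limma on the recovered reads called 56 genes (51 up, 5 down), among them all 7. Relb, a subunit of NF-κB, rose by 1.18 and Tnfaip3, a brake on the same pathway, by 1.26 in that fit, with adjusted p-values of 0.00498 and 0.00793. Small noncoding and mitochondrial ribosomal RNAs were also among those 56, and mt-Rnr2 rose by 1.31. Transcripts of replication-type histones, as of Hist1h1d and Hist1h1e, lack a poly(A) tail like many of these RNAs.

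Of the 28 measured genes of NF-κB signalling and inflammation, 28 had positive fold changes in KO islets, with a median of 0.70; 2 were called over all genes and 8 rose when adjusted over the list alone. The set test on the deposited Wald statistics gave an adjusted p of 1.6e-47, against an adjusted p = 0.319 with an estimated correlation. The 9 measured chemokine genes had a median of 1.38, 8 of them positive, with 1 call over all genes and 1 adjusted over the list alone (adjusted p 1.2e-19, adjusted p = 0.223 with an estimated correlation). For Cxcl1 and Cxcl11 the authors' deposited table gave 2.13 (SE 0.91) and 1.91 (SE 0.78), short of the threshold. Among 40 interferon-response genes 34 were positive, with a small median of 0.24 and 0 of the authors' calls, over all genes or adjusted over the list alone, against 1 in the limma fit with the mouse as a block (adjusted p 4.6e-11, adjusted p = 0.223 with an estimated correlation). Parp14 and Nlrc5 of this list stood at 0.24 (SE 0.12) and 0.78 (SE 0.36) in the authors' deposited table, neither past the threshold.

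The 8 measured lymphocyte genes were all positive (adjusted p 3.5e-24, adjusted p = 0.361 with an estimated correlation). Of the authors' calls over all genes they held 0, against 2 in the limma fit with the mouse as a block, and 2 adjusted over the list alone. Ptprc, the leukocyte marker CD45, stood at 1.33 (SE 0.34, FDR 0.154) in the authors' deposited table. Immediate-early genes had a median of 0.20 with 20 of 23 positive (adjusted p 2.0e-05, adjusted p = 0.446 with an estimated correlation). Oxidative-stress genes had a median of 0.07 with 15 of 20 positive (adjusted p 1.1e-06, adjusted p = 0.371 with an estimated correlation). Mt1 was called over all genes and 3 members rose when adjusted over the list alone. Proliferation genes had a median of 0.16 (adjusted p 4.4e-05, adjusted p = 0.319 with an estimated correlation). Macrophage genes had a median of 0.11 (adjusted p 0.00173, adjusted p = 0.535 with an estimated correlation), with median log2 changes of 0.21 in the female and -0.03 in the male mouse. Endothelial genes were 15 of 15 negative with a median of -0.12 (adjusted p 1.5e-05, adjusted p = 0.535 with an estimated correlation). The list of delta, PP and epsilon cell genes was called lower (adjusted p 0.00555, adjusted p = 0.446 with an estimated correlation) although 4 members were positive and 4 negative, with Ppy its 1 call over all genes and adjusted over the list alone. Immediate-early, proliferation, macrophage and endothelial genes held 0 calls over all genes, by the authors or in the limma fit with the mouse as a block, and 0 adjusted over the list alone.

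In Mut islets the same treatment left the inflammatory genes short of the authors' threshold. Cxcl10 stood at 2.14 (SE 0.51, FDR 0.130), Birc3 at 0.72 (SE 0.18, FDR 0.236), Nfkbia at 0.64 (SE 0.19, FDR 0.808) and Mt1 at 0.57 (SE 0.16, FDR 0.718) in the authors' deposited table. Unadjusted, 150 genes had a p below 0.05 there, again under the share expected without any effect (median p 0.70). The 2 genes called were the immunoglobulin segments Ighv12-3 and Igkv4-91. Both were listed at 0 in the untreated Mut libraries and in the treated male library, and the treated female library held 4.34 and 7.6 normalized counts. With the mouse as a block, limma called 28 genes (22 up, 6 down) and neither segment. Birc3 rose by 0.72, Relb by 1.05, Mt1 by 0.57 and Mt2 by 0.76 in that fit. Selp, the adhesion molecule P-selectin, rose by 2.57 and Il11, an IL6-family cytokine, by 1.33, while Bhlha15, an acinar secretory transcription factor, fell by 0.50.

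The 28 genes of NF-κB signalling and inflammation had a median of 0.61 in Mut islets, 27 positive, with 0 of the authors' calls over all genes, 5 in the limma fit with the mouse as a block and 5 adjusted over the list alone (adjusted p 2.6e-31, adjusted p = 0.382 with an estimated correlation). Chemokines had a median of 0.74 with 0 calls over all genes, by the authors or in the limma fit with the mouse as a block, and 1 adjusted over the list alone (adjusted p 1.2e-08, adjusted p = 0.382 with an estimated correlation). Interferon-response genes had a median of 0.24, 36 of 40 positive, with 0 calls over all genes in either and 1 adjusted over the list alone (adjusted p 2.8e-11, adjusted p = 0.312 with an estimated correlation). Immediate-early genes had a median of 0.32 (adjusted p 1.1e-07, adjusted p = 0.444 with an estimated correlation). Oxidative-stress genes had a median of 0.10 (adjusted p 0.000376, adjusted p = 0.444 with an estimated correlation), with 2 rising when adjusted over the list alone. Apoptosis genes had a median of 0.14 (adjusted p 0.0416, adjusted p = 0.444 with an estimated correlation). These changes were larger in the Mut female than in the Mut male. Female before male, median log2 changes were 0.42 and 0.09 for immediate-early, 0.13 and -0.004 for oxidative-stress and 0.21 and 0.03 for apoptosis genes. Macrophage genes had a median of 0.17 (adjusted p 0.00392, adjusted p = 0.565 with an estimated correlation). This rested on the female mouse, with a median log2 change of 0.37 against -0.03 in the male.

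For markers of stromal, acinar, endothelial and beta cells the authors called 0 genes between the untreated and treated Mut libraries. All 18 stromal genes were positive with a median of 1.34 (adjusted p 2.1e-23, adjusted p = 0.444 with an estimated correlation), with Dcn at 1.58 (SE 0.61) and Col6a1 at 1.72 (SE 0.65) in the authors' deposited table. This rested on the female mouse, whose stromal reads went from 0.0312% to 0.104% of recovered normalized counts, while those of the male went from 0.0279% to 0.0331%. All 22 acinar genes were negative with a median of -1.02 (adjusted p 2.8e-08, adjusted p = 0.444 with an estimated correlation), with 0 of the authors' calls over all genes. Bhlha15 was the 1 call in the limma fit with the mouse as a block and adjusted over the list alone. Endothelial genes were 15 of 15 positive with a median of 0.22 (adjusted p 1.1e-07, adjusted p = 0.494 with an estimated correlation). Beta-cell genes had a median of -0.07, 25 of 31 negative (adjusted p 0.000336, adjusted p = 0.517 with an estimated correlation), with Ins2 at -0.24 (SE 0.09) and Ins1 at -0.18 (SE 0.10) in the authors' deposited table. ER-stress genes had a median of -0.11, 21 of 26 negative (adjusted p 3.3e-06, adjusted p = 0.382 with an estimated correlation). Calcium and exocytosis genes had a median of -0.03 (adjusted p 0.043, adjusted p = 0.449 with an estimated correlation).

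**Figure D2:**
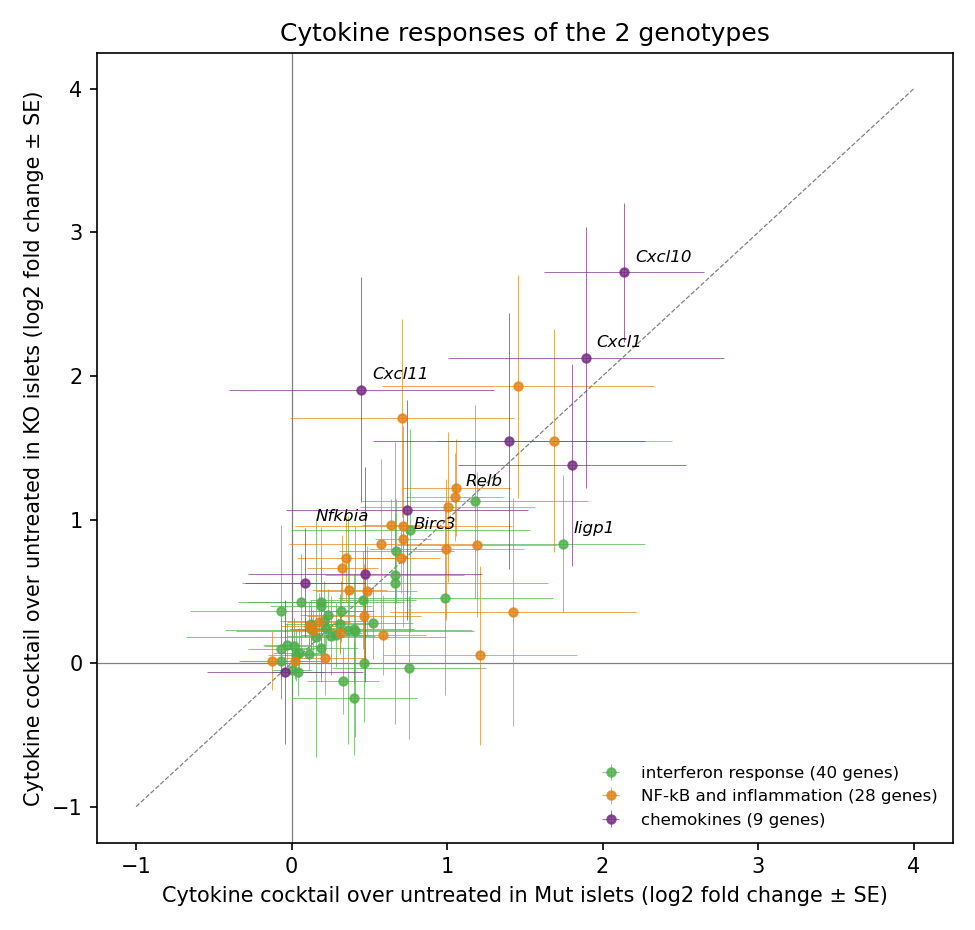
Log2 fold change of cytokine cocktail over untreated in Mut islets (horizontal axis) and KO islets (vertical axis) for the measured members of 3 gene lists, as given in the authors' deposited tables. Points are genes, bars are standard errors and the dashed line marks equal responses; Cxcl10 lies at 2.14 and 2.72, and most members of the list of NF-κB and inflammation lie above 0 on both axes.

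Whether the response to cytokines differed by genotype was tested as the difference of the 2 deposited fold changes. It gave 0 genes at an adjusted p below 0.05, with a smallest adjusted p of 0.999989. Unadjusted, 36 had a p below 0.05, under the share expected without any effect, with a median p of 0.774. The test ran conservative, so 0 calls do not show that the responses were alike. The linear models of limma on the recovered reads also gave 0, with the mouse as a block (713 unadjusted) or without (107 unadjusted). Among genes with a mean of at least 50, the smallest p-values belonged to Ighv12-3, Igkv4-91, Ppy, Ptprc, Eif3j2 and Myo1g. The KO response minus the Mut response was -0.65 (SE 0.22) for Ppy and 1.32 (SE 0.49) for Ptprc. It was 0.58 (SE 0.71) for Cxcl10, 0.20 (SE 0.14) for Ins1 and 0.26 (SE 0.12) for Ins2, and none of these passed. A call in KO and not in Mut islets is therefore no evidence of a different response.

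The authors' calls of the cytokine responses shared 0 genes between genotypes (Fisher's exact test, p = 1 for higher genes). Among lower genes, with 1 call in KO and 0 in Mut, no overlap was possible. With the mouse as a block, 11 higher genes were called in both, where independent lists would share 0.069 (Fisher's exact test, p = 6.2e-23), and 1 lower gene (expected 0.00184, Fisher's exact test, p = 0.00184). Both lists came from 1 fit with a single residual variance per gene, so a gene of small variance is favoured in both. They are thus not independent lists, and these p-values do not measure sharing alone. Of the 56 genes called in KO islets 47 had the same direction in Mut islets, and of the 28 called in Mut islets 27 had the same direction in KO islets. A fit of both genotypes together, with the mouse as a block and 1 cytokine term, called 186 genes (134 up, 52 down). Cxcl10 rose by 2.59, Nfkbia by 0.82, Relb by 1.12, Birc3 by 0.81, Il6 by 1.69, Cxcl1 by 1.97 and Irf1 by 0.29 in that fit, and Txnip, a glucose-responsive inhibitor of thioredoxin, fell by 0.37. Without the KO female, KO male or Mut male mouse that count was 67, 69 or 78, and without the Mut female it was 237.

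The untreated comparison of KO with Mut islets asks how the mice of the 2 genotypes differed before any cytokine was added. Whether the Mut mice carried the construct through which tamoxifen acts is not given, so its effects and those of the deletion were not separated. Of 28 measured proliferation genes 4 were called higher in KO islets. Top2a, the topoisomerase of dividing cells, was 3.17-fold higher (log2 1.67, SE 0.21, FDR 3.0e-11), the proliferation marker Mki67 3.59-fold (log2 1.84, SE 0.23, FDR 1.4e-11) and the spindle motor gene Kif11 4.75-fold (log2 2.25, SE 0.38, FDR 1.0e-05) in the authors' deposited table. Top2a held 396 and 343 normalized counts in the KO libraries against 118 and 115 in the Mut libraries. Ptger3, the prostaglandin E receptor EP3, was 4.55-fold higher (log2 2.19, SE 0.25, FDR 4.1e-14) and Hmgcs1, an enzyme of cholesterol synthesis, 1.76-fold higher (log2 0.82, SE 0.10, FDR 1.7e-11) in the authors' deposited table.

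Lower in KO islets were Insm1, a transcription factor of endocrine cells, at -0.56 (SE 0.11), Chac1, a glutathione-degrading enzyme of the unfolded protein response, at -0.99 (SE 0.23), and Vgf, a secretory granule protein, at -0.60 (SE 0.15) in the authors' deposited table. Also called lower there were Sgcd at -1.62 (SE 0.34), Prom1 at -1.22 (SE 0.29), Tmc7 at -0.85 (SE 0.22), Srrm4 at -0.85 (SE 0.23), Cntnap2 at -0.62 (SE 0.17) and Erdr1 at -3.34 (SE 0.83) in the authors' deposited table. Erdr1 rested on the Mut mice, whose libraries held 459 and 57.3 normalized counts untreated against 25.8 and 25.1 in KO. Ins1, Ins2, Gcg and Sst, the main islet hormone genes, stood at -0.15 (SE 0.09), -0.06 (SE 0.11), -0.05 (SE 0.57) and -0.45 (SE 0.51) in the authors' deposited table, none of them called.

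The largest fold changes belonged to genes of antibody-producing cells. Ighm and Igkc, the heavy and light chain constant regions, stood at 8.99 (SE 1.63) and 9.12 (SE 1.61), and Jchain, the joining chain of antibodies, at 9.42 (SE 1.89) in the authors' deposited table. Ighm held 17557 and 3983 normalized counts in the female and male KO libraries against 25.3 and 17.2 in Mut. Immunoglobulin segments took 0.191% and 0.0528% of recovered normalized counts in these KO libraries and at most 0.00127% in any Mut library. The segments Igkv14-126 and Ighv1-11, also called, were listed at 0 in the Mut libraries, and Ighv1-11 at 0 in the KO male library as well, so their fitted folds are not given. Pou2af1, Irf4 and Ms4a1, which act in B cells, stood at 6.33 (SE 1.24), 5.28 (SE 1.04) and 4.43 (SE 1.18), and Cyp1b1, a cytochrome P450, at 5.67 (SE 1.48) in the authors' deposited table. The 67 calls of this comparison, 58 higher and 9 lower, held 5 immunoglobulin segments.

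Proliferation genes had a median of 0.54, 21 of 28 positive, with 4 calls over all genes and 9 adjusted over the list alone (adjusted p 4.2e-21, adjusted p = 0.0969 with an estimated correlation). Lymphocyte genes had a median of 1.41, with 1 call over all genes and 5 adjusted over the list alone (adjusted p 1.5e-11, adjusted p = 0.272 with an estimated correlation). Macrophage genes were 16 of 16 positive with a median of 0.63, with Lyz2 called at 1.06 (SE 0.28) in the authors' deposited table and 9 rising when adjusted over the list alone (adjusted p 3.2e-15, adjusted p = 0.272 with an estimated correlation). Stromal genes had a median of 1.74, with Dcn (2.36, SE 0.54) and Postn (1.85, SE 0.48) called in the authors' deposited table and 8 adjusted over the list alone (adjusted p 9.6e-14, adjusted p = 0.272 with an estimated correlation). Oxidative-stress genes were called higher (median 0.04, adjusted p 0.000832, adjusted p = 0.272 with an estimated correlation), with Mt2 called at 0.82 (SE 0.20) in the authors' deposited table and 4 adjusted over the list alone, although 10 members were positive and 10 negative. Duct genes had a median of 0.20 with 0 calls over all genes, by the authors or in the limma fit with the sex covariate, and 2 higher and 1 lower adjusted over the list alone (adjusted p 0.00932, adjusted p = 0.272 with an estimated correlation).

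In untreated KO islets 14 of 15 endothelial genes were negative with a median of -0.32, with 0 of the authors' calls over all genes, 1 in the limma fit with the sex covariate and 4 adjusted over the list alone (adjusted p 2.0e-11, adjusted p = 0.295 with an estimated correlation). The vascular growth factor receptors Flt1 and Kdr stood at -0.49 (SE 0.14, FDR 0.0665) and -0.76 (SE 0.22, FDR 0.112) in the authors' deposited table. ER-stress genes had a median of -0.13, 20 of 26 negative, with Chac1 as the 1 call over all genes and adjusted over the list alone (adjusted p 2.7e-05, adjusted p = 0.464 with an estimated correlation). Heat-shock genes had a median of -0.17, 12 of 14 negative, with 0 calls over all genes by the authors or limma and 2 adjusted over the list alone (adjusted p 0.000355, adjusted p = 0.272 with an estimated correlation). Endothelial reads made up 0.0509% and 0.0441% of recovered normalized counts in the KO libraries and 0.0622% and 0.0694% in the Mut libraries.

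At an unadjusted p below 0.05 the authors' deposited table held 798 genes for the untreated comparison, just under the share of 0.05 expected without any effect. With the sex of the mouse as a covariate, limma called 273 genes (190 up, 83 down), among them 51 of the 66 authors' calls with recovered reads, and without the covariate it called 0. The 273 became 0 without either untreated Mut library, 53 without the untreated KO male and 126 without the untreated KO female library, and 623 and 627 without the treated female and male Mut libraries.

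With cytokines, the authors' deposited table held 163 calls between the genotypes, 133 higher and 30 lower, of which 10 were immunoglobulin segments. At an unadjusted p below 0.05 it held 960 genes, near the share of 0.05 expected without any effect. The interaction test called 0 genes, so the larger count of calls is no evidence of a wider genotype difference. Top2a was 3.86-fold higher in KO islets (log2 1.95, SE 0.21, FDR 4.9e-17), Mki67 3.9-fold (log2 1.96, SE 0.22, FDR 1.2e-14), Ptger3 4.31-fold (log2 2.11, SE 0.24, FDR 2.5e-14) and Kif11 3.47-fold (log2 1.80, SE 0.36, FDR 0.000322) in the authors' deposited table. Ptprc was 5.39-fold higher (log2 2.43, SE 0.32, FDR 8.4e-11), with 742 and 1089 normalized counts in the KO libraries against 151 and 188 in Mut. Cxcl10 was 2.91-fold higher in KO than in Mut islets after cytokines (log2 1.54, SE 0.42, FDR 0.0308) in the authors' deposited table, against 0.92 (SE 0.47, FDR 1) untreated. No difference by genotype in the response of Cxcl10 to cytokines was called in the test above.

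In treated KO islets 9 of 15 endothelial genes were called lower. Flt1 stood at -0.77 (SE 0.14), Kdr at -1.08 (SE 0.22) and Eng, a coreceptor for TGFβ family ligands on vessels, at -1.18 (SE 0.25) in the authors' deposited table. Kdr held 1280 and 874 normalized counts in KO against 2255 and 2300 in Mut. Of the 15 measured endothelial genes 15 were negative with a median of -0.77. Adjusted over the list alone, 13 were lower (adjusted p 2.4e-36, adjusted p = 0.251 with an estimated correlation). Also called lower in the authors' deposited table were the clock gene Npas2 at -1.59 (SE 0.38), the extracellular matrix gene Reln at -2.16 (SE 0.60) and Pgr, the progesterone receptor, at -3.47 (SE 0.97). Cyyr1 stood at -1.29 (SE 0.31), Sema3g at -1.24 (SE 0.35), Sgcd at -1.40 (SE 0.34) and Tmc7 at -1.05 (SE 0.22) among the lower calls of the authors' deposited table.

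In treated KO islets 7 of 8 lymphocyte genes were called higher over all genes and 8 adjusted over the list alone, with a median of 2.54 (adjusted p 2.8e-35, adjusted p = 0.251 with an estimated correlation). Cd22 stood at 3.36 (SE 0.64), Ms4a1 at 5.70 (SE 0.93), Pou2af1 at 6.71 (SE 1.01) and Irf4 at 5.52 (SE 0.92) in the authors' deposited table. Ighm, Igkc and Jchain stood at 7.68 (SE 1.62), 8.08 (SE 1.58) and 8.07 (SE 1.75) in the authors' deposited table, with immunoglobulin segments at 0.305% of recovered normalized counts in the KO female and 0.0132% in the KO male library. Igkv14-126 and Ighv1-11 were again called and listed at 0 in the treated Mut libraries, and Ighg3, a further constant region, was called as well and listed at 0 in all Mut libraries. Macrophage genes had a median of 0.52, with Lyz2 (1.46, SE 0.28), Laptm5 (1.16, SE 0.22) and Cd53 (1.35, SE 0.34) called in the authors' deposited table and 5 adjusted over the list alone (adjusted p 8.1e-14, adjusted p = 0.251 with an estimated correlation).

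Proliferation genes had a median of 0.70, 25 of 28 positive, with 5 calls over all genes and 13 adjusted over the list alone (adjusted p 1.4e-27, adjusted p = 0.0565 with an estimated correlation). Oxidative-stress genes had a median of 0.10 (adjusted p 0.000233, adjusted p = 0.291 with an estimated correlation), with 4 calls over all genes, and 5 higher and 1 lower adjusted over the list alone. Mt1 stood at 0.68 (SE 0.15), Mt2 at 0.88 (SE 0.20) and Gpx3 at 0.57 (SE 0.14) in the authors' deposited table. Duct genes had a median of 0.27 (adjusted p 0.00291, adjusted p = 0.301 with an estimated correlation), with 1 call, Krt8 at 0.84 (SE 0.21) in the authors' deposited table, and 2 higher and 1 lower adjusted over the list alone. Heat-shock genes had a median of -0.17, 12 of 14 negative (adjusted p 0.00146, adjusted p = 0.251 with an estimated correlation). They held 0 calls over all genes by the authors or limma, and 0 adjusted over the list alone. Acinar genes were 22 of 22 positive with a median of 2.02 (adjusted p 9.0e-09, adjusted p = 0.291 with an estimated correlation). Of the authors' calls they held 0, over all genes or adjusted over the list alone, against 13 in the limma fit with the sex covariate. Acinar reads made up 0.977% and 0.18% of recovered normalized counts in the female and male KO libraries and 0.231% and 0.0523% in those of Mut, so the sexes differed by more than the genotypes.

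With the sex covariate limma called 584 genes (391 up, 193 down), among them 151 of the 161 authors' calls with recovered reads, against 2 without it. The 584 became 109 without the treated KO male, 186 without the treated KO female, 247 and 248 without the untreated female and male Mut libraries, and 393 without the treated Mut female library.

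Genotype calls recurred across treatment: 43 genes were called higher in both comparisons, where independent lists would share 0.472 (Fisher's exact test, p = 2.0e-80), and 4 lower in both (expected 0.0165, Fisher's exact test, p = 1.2e-09). The same 4 mice gave both comparisons, so the overlap holds for these mice and is no independent repeat. The list of alpha-cell genes was not called from the deposited statistics in any comparison, with medians of 0.02 and 0.05 for the cytokine responses in KO and Mut and -0.11 and -0.09 for the genotype differences. With the sex covariate, limma called 1 alpha-cell gene lower in each genotype comparison and the list lower with the preset correlation (adjusted p 0.0117 and 0.0452, adjusted p = 0.272 and 0.297 with an estimated correlation). That fit and correlation also called the beta-cell list lower (adjusted p 0.00561 and 0.0452, adjusted p = 0.272 and 0.319 with an estimated correlation), whose deposited medians were -0.07 and -0.04. Untreated, they called acinar genes higher (adjusted p 1.9e-07, adjusted p = 0.398 with an estimated correlation) and interferon-response genes higher (adjusted p 0.0459, adjusted p = 0.528 with an estimated correlation). Calcium and exocytosis genes were called lower there (adjusted p 0.0471, adjusted p = 0.272 with an estimated correlation). With the mouse as a block, the KO cytokine response gained the acinar list as higher (adjusted p 0.00888, adjusted p = 0.625 with an estimated correlation), the apoptosis list as higher (adjusted p 0.0202, adjusted p = 0.441 with an estimated correlation) and the beta-cell list as lower (adjusted p 0.0202, adjusted p = 0.535 with an estimated correlation). Acinar genes moved opposite ways in the KO mice, with median log2 changes of 0.76 in the female and -0.48 in the male. From the deposited statistics the list of genes encoded by mitochondria was not called either, with medians of 0.08, -0.09, -0.00 and 0.15 in the same order, nor were the 5 measured sex-linked genes, with medians of -0.05, 0.19, 0.04 and -0.12. The list of erythroid genes, Nos2, Tnf, Il15 and Cxcl9 were not analysed here.

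**Figure D3:**
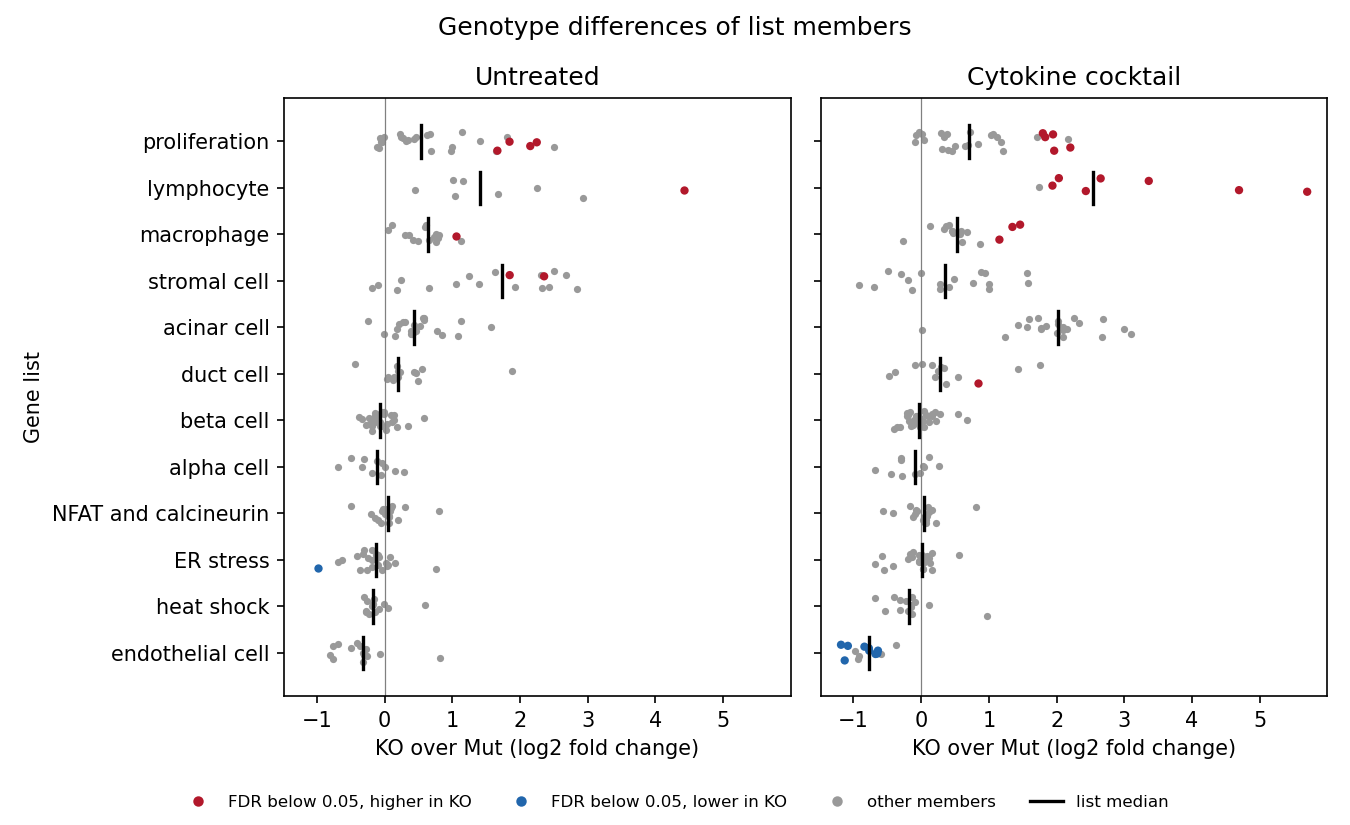
Log2 fold change of KO over Mut (horizontal axes) for the measured members of 12 gene lists (vertical axis), untreated and with cytokines, as given in the authors' deposited tables. Points are genes, red and blue points passed an FDR of 0.05 as higher and lower in KO, grey points did not, and black bars are list medians; the endothelial median was -0.32 and -0.77 and the acinar median 0.43 and 2.02 in the panels.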

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

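Tests chosen only after the result was seen are those of B-lineage genes, of the KO male mouse, of Esr1 reads and of nuclear small RNAs. The interaction test of lists was added after the data had been seen too. The tests of T-lineage genes, lactogen-responsive genes, dividing B-lineage cells and mitochondrial messenger RNAs were set before their values were seen.

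In 2 of 23 lists, looked at together with 9 single genes, the mice of the 2 genotypes moved opposite ways with cytokines. The 23 lists here had at least 5 genes with recovered reads, and some were added after the data were seen. With 2 mice per genotype, random directions alone would give such opposite moves in some lists. Endothelial genes had a median log2 change of -0.0615 and -0.235 in the KO female and male mouse, against 0.408 and 0.0501 in the Mut female and male. ER-stress genes had medians of 0.015 and 0.0113 in the KO female and male, which barely moved, against -0.138 and -0.0385 in the Mut female and male. For the difference between genotypes, camera of limma with the mouse as a block gave adjusted p-values of 2.7e-12 and 2.1e-07 with the preset correlation. With an estimated correlation both were 0.495, and the rotation test fry gave 0.578 for both, so neither of these tests called the difference. For ER-stress genes the correlation estimated with this block was 0.03 in the cytokine response of either genotype. The lost call is therefore not laid to correlation alone.

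The authors called 5 and 10 immunoglobulin segments in the genotype comparisons untreated and with cytokines, all higher in KO. That 1 KO mouse alone made the difference is argued against by the KO male, whose summed immunoglobulin counts lay 43.7-fold untreated and 10.9-fold with cytokines above the highest Mut library. B-lineage cells in the KO preparations fit the result, since 9 B-lineage genes other than immunoglobulin segments had a median log2 fold change of 4.28 untreated (range 0.43 to 9.19). Yet 5 of them were calls already seen untreated and 7 with cytokines, so they give no independent test. Whole lymphoid tissue carried over with the islets cannot be told apart: Lck, Tcf7 and Il7r had a median of 0.34, under the limit of 0.5 set beforehand for ruling it out, but their range of 0.20 to 1.01 crosses that limit, and the condition on the range was applied only after the median was seen. All 4 measured genes of the T-lineage list, written after the data were seen, had medians of 0.68 untreated and 1.28 with cytokines in the same fit. Whether such cells entered islets in the living mice because of the deletion, or came with the dissection, was not tested.

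The authors called 4 and 5 of 28 proliferation genes higher in KO islets, untreated and with cytokines. The list call was lost with an estimated correlation (adjusted p = 0.0969 and 0.0565). The rotation test fry called the list in both (adjusted p = 0.0042 and 0.0016), in the fit that treats the libraries of a mouse as independent. Esr1, the estrogen receptor α gene, was called only in the limma fit with the sex covariate. Stronger signalling of the lactogen type in KO islets fits the values of 10 lactogen-responsive genes. That list was added after the data were examined but before these values were looked up. Its median log2 fold change was 0.83 untreated (0.12 to 1.67, all positive). The authors called 0 of the 10 untreated, and the median was 0.71 without Lrrc55, their 1 call among them with cytokines. Centred per gene over all libraries, the log2 median of the list was 0.11 and 0.66 in the untreated KO female and male, against -0.82 and 0.04 in Mut. The Mut mice thus differed about as much as the genotypes, and the Mut male lay near the KO female. The list was tested with the preset correlation only. Dividing B-lineage cells are argued against by the proliferation list, in which the KO female exceeded the KO male by 0.18 untreated and 0.00239 with cytokines on the log2 scale, where immunoglobulin counts differed 3.53-fold and 22.7-fold, and the KO male lay 0.47 and 0.65 above the higher Mut library. They cannot be told apart all the same, since the untreated 0.47 is under the bound of 0.5 set beforehand and B-lineage genes did not move as 1: in the treated KO female and male, 9 of them summed to 5368 and 1792 normalized counts, while Ms4a1 (110 and 90) and Cd22 (118 and 114) were alike. Reads of an estrogen receptor domain in a tamoxifen-inducible Cre construct, counted as Esr1, cannot be told apart either, as Esr1 was 1.77-fold to 2.25-fold higher in KO for each sex and treatment, was also high in Mut (98.4th percentile or above), and no counts per exon were analysed.

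In the limma fit with the mouse as a block, mitochondrial ribosomal RNAs and some small noncoding RNAs were called higher in KO islets with cytokines; the deposited changes of mt-Rnr1 and mt-Rnr2 were 1.28 to 1.49 on the log2 scale, neither called by the authors. More mitochondrial RNA in general is argued against, since 10 mitochondrial messenger RNAs had a median change of 0.0776 (quartiles -0.03 to 0.10). Uneven capture of RNA without a poly(A) tail cannot be told apart: 8 nuclear small RNAs had median changes of 0.45 in the KO female and 0.64 in the KO male, but 3 of them were calls that belong to the pattern itself, so their rise is no test of it. The linker histone gene Hist1h1d also rose in the Mut female and male, by 0.33 and 0.47 on the log2 scale, and Hist1h1e by 0.57 and 0.43. The nuclear small RNAs moved there by 0.15 and -0.06, so uneven capture as seen in KO does not account for the histone rise in Mut. For the larger rise of Hist1h1d in KO islets (0.82 and 0.87) uneven capture stays open. A biological effect of the cytokines on the mitochondrial ribosomal and small noncoding RNAs in KO islets stays open and was not tested.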

How the results depend on the processing

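All fits of recovered reads, and the settings that leave out a library, a mouse or the immunoglobulin segments, were chosen only after the data had been seen. The cause of the moves below was not tested, except where fewer samples or a stricter threshold make it plain.

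The 7 calls of the cytokine response in the NFATc2 knockout became 1 with an absolute log2 fold change of at least 1, 0 with limma voom without a block, 56 with the mouse as a block and 186 with both genotypes together, and 0 to 1 with each library left out of the fit of group means. The 2 calls in Mut became 0, 28 and 186 with the same fits, and 0 with any library left out of the fit of group means. With the sex covariate as well, leaving out a library gave up to 8 calls in the knockout and 4 in Mut. The 67 calls of the untreated genotype difference became 39 at an adjusted p below 0.01, 0 with limma voom, 273 with the sex covariate, and 0 to 627 over the fits that leave out a library. The 163 calls of the genotype difference with cytokines became 93 at an adjusted p below 0.01, 103 with a mean of at least 50, 2 with limma voom, 584 with the sex covariate, and 0 to 575 over the fits that leave out a library. Without the KO female mouse the sex covariate gave 1012 and 1326, with 1 residual degree of freedom, and 61 genes for the interaction, which was 0 in the fits of all libraries; these counts rest on too few samples to be relied on. The 40 list calls became 0 with an estimated correlation, and the 0 cytokine calls shared between genotypes became 12 with the mouse as a block.

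Directions reversed for 3 immunoglobulin segments when the only library with reads in its group was left out. The Mut response was -0.57 for Ighv12-3 and -0.57 for Igkv4-91 without the treated Mut female, against at most 2.99 and 3.72 with another library left out. The untreated genotype difference of Ighv1-11 was -0.74 without the untreated KO female, against at most 10.1. For named genes, leaving out a library from the fit of group means kept 720 results on their side of the threshold and lost 557 calls, but that fit already called 0, 0, 0 and 2 genes with all libraries, so the loss is not laid to the left-out library. From the fit with the sex covariate, 465 kept it, 57 gained and 182 lost it, again with the fit and the library changed together. With the mouse as a block 61 kept it, 9 gained and 2 lost it. With the sex covariate 68 kept it, 8 gained and 12 lost it. Ranks kept 80 list results, gained 4 calls and lost 4. The preset correlation of 0.05 kept 86 and lost 2, and a mean of at least 50 kept 78 and lost 2.

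A left-out library leaves 1 in its group, which is then assumed to vary like the others. Pairs of libraries joined by sex are pairs by mouse only if the 2 mice of a genotype differ in sex, as the Y-linked genes show. Of the planned settings, those for deposited library columns (another size factor, a count model of their own and another pseudocount) were not run, since the tables hold none. They were not tried on the recovered reads either, for which limma voom alone was used.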

Other observations

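The split of the libraries by treatment was set against other splits before its result was seen, and the remaining values here were chosen after the data had been seen.

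With both genotypes together and the mouse as a block, the real split into untreated and treated libraries gave 186 calls. Of the 8 splits that part every pair of libraries of a mouse, only 1, the real one, gave as many, and the highest of the others gave 9. With 8 splits the smallest possible share is too large for a permutation test at 0.05, so a chance split cannot be told apart by this test.

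Esr1 held 17451 and 41261 normalized counts in the untreated KO female and male, and 9865 and 19048 in the Mut female and male. Tph1, which makes the precursor of serotonin and responds to lactogens in islets, held 8558 and 17914 against 1856 and 6920. Pgr held 20.5 and 3.7 against 51.8 and 221. The Y-linked genes summed to 46.9 normalized counts in the treated KO female, 0.53% of the treated KO male. The authors marked 10 genes as disallowed, none of which was called.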
